A study of Mus musculus with 2 samples.

How the data were processed

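Chromatin accessibility was measured by DNase-seq in hearts of female B6CASTF1/J mice, hybrids of the B6 and CAST strains, at 14 days of age. The labels give 2 biological replicates with separately numbered animals but the same donor record for both. They were treated as 2 hearts, and if they were not from separate animals the SDs and ratios measure technical spread. Each had 1 library and there was no second group, so no test between groups was made.

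For each library a longer and a stricter peak list, a list of footprints and a list of false discovery rates per base were used, all made per library from an alignment to mm10, per the file headers. The aligner and the caller are not given in the sources used here. The deposited peak value is a signal that is never negative. In each library 100% of the values were whole multiples of 1 step within 0.05 steps, with a step of 0.00576 in replicate 1 and 0.00842 in replicate 2, so the values carry a library-specific scaling whose form is not stated. The number of reads is unknown and no interval for counting error was computed. The deposited rates per base are values of the p-value or q-value kind, listed where they are under 0.05, and the footprint lists give the same value on every line. Every peak of the longer lists held a base with a rate under 0.05, and every peak of the stricter lists (106361 and 107417 peaks) a base under 0.001. The animals carry CAST alleles and mm10 is a B6 genome, so reads from CAST alleles could be lost in alignment, which was not measured here.

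The list with the narrower median width was to be the main one. Both medians were 180 bp, and the mean width broke the tie (194.8 against 195.2 bp in replicate 1 and 184.0 against 185.3 bp in replicate 2), which made the longer list the main one. Genes came from the GENCODE vM21 annotation and sequence from GRCm38, the assembly that mm10 denotes. Peaks were shared at an overlap of 1 bp, and 100 random placements were drawn with bedtools 2.31.1. Shared regions were unions of overlapping peaks of both libraries, with the highest peak value per library. A promoter was 1000 bp on each side of any annotated start site of a gene, and the promoter value was that of its strongest peak there, which can also belong to a neighbouring gene. Promoters were said to overlap where start sites of 2 protein-coding genes lay within 2000 bp. A value of 0 means that no peak was listed. Distal regions lay over 1000 bp from any start site.

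Gene lists (25), consensus motifs (30), tests and most alternatives were fixed before the data were examined; 1 listed symbol had no match in the annotation. Lists were compared with the other protein-coding genes by two-sided Fisher's exact tests and medians with 10000 random lists, matched on gene length for distal counts and on mean value for ratios between libraries, with Benjamini-Hochberg adjustment over lists. The CpG-matched background used the CpG content of 500 bp on each side of the gene's 5′ end in 10 classes. Motifs were searched on both strands, and the exact binomial test used windows where only the peak or only the right flank had a match. GC-matched windows were drawn from 300000 random positions. The genes named were anchor genes fixed in advance, up to 3 genes per list with the highest promoter value, up to 3 without a peak in lists where most genes had one, up to 3 per heart list with the most distal regions, the 5 strongest shared peaks and the 5 strongest peaks of each library alone. Other genes, such as Tie1, Cdh5, Nos3, Gad1 and Cd3d, were chosen after their values were seen. Some genes that the rule names are not reported here.

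Alternatives were other promoter windows, the 5′ end alone, the stricter list, the stronger part of each list split at its median value, a reciprocal overlap of 50%, equal numbers of peaks, other reaches and window widths, matched backgrounds, other centring and leaving out each library. Summed cut counts per peak were not analysed here. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.

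The procedures were tested on simulated data. A planted overlap of 80% among 10000 peaks was recovered as 80%. Of 500 lists with an open share of 95% among genes at 70%, 54.6% were called, as were 0.526% of 1900 unchanged lists. A log2 shift of 0.3 between libraries reached an unadjusted permutation p under 0.05 in 52% of 100 lists, and no shift in 4%, so shifts of that size could be missed in the simulation. The simulated spread of ratios was wider than the SD of 0.40 in these data, and lists were not matched on value. The 52% need therefore not hold here. Matches planted in 10% of 5000 windows were found in 10.02%.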

Results

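DNase-seq, which maps open chromatin from the places where the enzyme DNase I cuts DNA in nuclei, was performed on hearts of female mice of the hybrid strain B6CASTF1/J at 14 days of age. The series held 1 group of 2 hearts with 1 library each. The comparisons were therefore made between the 2 hearts and, within each library, between gene lists, sequence motifs and chromosomes. The longer peak list held 166466 peaks in replicate 1 and 161690 in replicate 2, with a median width of 180 bp in both, and covered 32.0 Mb and 29.6 Mb. The deposited signal of a peak, called the peak value here, had a median of 0.680 in replicate 1 and 0.851 in replicate 2. The number of reads behind it is unknown. Promoter values of genes are given as the mean ± SD of the 2 libraries (n = 2) unless a library is named, and coordinates are 1-based on mm10. These values are not centred, and promoters had a median log2 ratio of replicate 2 to replicate 1 of 0.43. The SDs of gene values therefore include this common shift and do not rank genes by their agreement between the hearts.

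The 2 hearts shared most accessible sites, and the strongest were shared almost completely. In replicate 1, 77.4% of peaks overlapped a peak of replicate 2 by at least 1 bp, and in replicate 2 79.8% overlapped a peak of replicate 1. Random placement gave 2.47% on average and 2.56% at most in 100 draws. Overlap rose with the peak value, from 27.4% in the lowest decile to 99.6% in the highest in replicate 1 and from 39.5% to 99.4% in replicate 2. Across 126584 shared regions the log2 values of the 2 libraries had a Pearson correlation of 0.947 and a Spearman correlation of 0.929. The Pearson correlation was 0.973 over promoter regions and 0.914 over distal regions. These describe agreement across regions, which are not independent replicates. After centring, 95.8% of the shared regions differed by less than 2-fold. Single bases listed with a false discovery rate under 0.05 covered 52.6 Mb and 49.2 Mb, and 41.2 Mb were listed in both libraries.

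**Figure D1:**
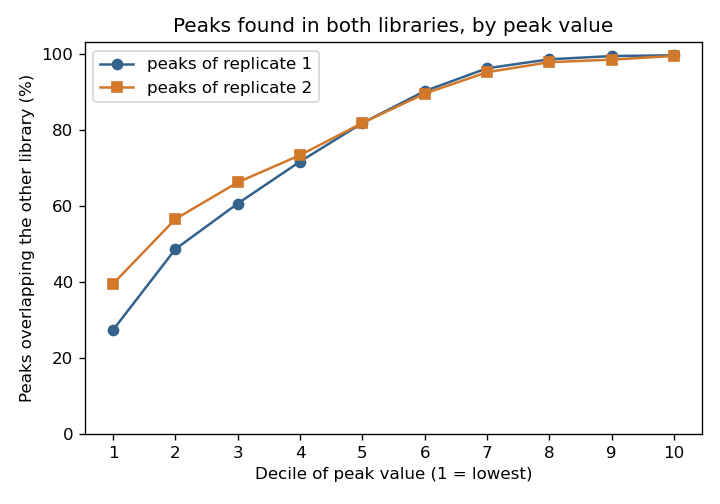
Share of peaks (%, y axis) that overlap a peak of the other library by at least 1 bp, for each decile of peak value (x axis, 1 is the lowest), with 1 line per library. The share rises from 27.4% to 99.6% in replicate 1 and from 39.5% to 99.4% in replicate 2.

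Accessible sites were concentrated at promoters. Within 1000 bp of an annotated start site lay 25.8% ± 0.249 of peak centres (SD, n = 2), 4.26-fold the share of the genome in that class, which was 6.05%. Coding exons held 1.95% ± 0.115 of peaks, 2.06-fold their share of the genome. Introns held 37.8% ± 0.347, close to their 38.3% of the genome, and intergenic sequence held 31.5% ± 0.0667, against 52.4% of the genome. Promoter peaks had the highest median value of the 5 classes, 1.24 in replicate 1 and 1.62 in replicate 2, and intergenic peaks the lowest, 0.553 and 0.682. The strongest shared region by mean value lay 8 bp from a start site of Hjurp, which encodes a chaperone of centromeric histones, on chromosome 1 (88277521 to 88277760), with values of 48.9 and 76.0. On chromosome 17 a region 117 bp from the start of Gm42418 (39846781 to 39846900) had 78.4 in replicate 1 and 39.8 in replicate 2, and a region 1 bp from a start of Dynlt1b (6430021 to 6430200) had 35.2 and 76.9. A region 7 bp from a start of 2610005L07Rik on chromosome 8 (20424721 to 20424920) had 53.8 and 48.6. In an untranslated or non-coding exon of Lars2 on chromosome 9 (123461921 to 123462080) the values were 63.7 and 29.4. Whether reads from repeated sequence raised the values of these regions was not measured, so they need not be the most accessible sites.

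Promoters of the contractile apparatus and of energy supply were open in both hearts. All 25 sarcomere genes had a promoter peak in both libraries, and so did all 22 genes of fatty acid oxidation and energy supply. Myom1, a protein of the M-band, had the highest value of the sarcomere list (23.6 ± 8.20), followed by the tropomyosin gene Tpm1 (21.1 ± 8.48). Myh6, the adult cardiac myosin heavy chain, had 2.92 ± 1.37, from a peak over the 5′ end of the gene on chromosome 14 (54966521 to 54967069 in replicate 1). The thin filament genes Tnnt2, Tnni3 and Actc1 had 2.72 ± 1.02, 2.90 ± 0.134 and 2.64 ± 0.0769, the Z-disc gene Actn2 had 5.98 ± 2.05 and the titin gene Ttn 3.46 ± 0.765. Of the energy genes, Acsl1, which activates fatty acids, had 22.2 ± 7.59, Acadm 20.1 ± 5.83, Cpt2 14.3 ± 2.58, the muscle creatine kinase gene Ckm 6.52 ± 0.363 and Cpt1b 2.87 ± 1.33. The promoter windows of Myom1, Ckm and Cpt1b overlapped those of other genes. In all this held for 4 of the 25 sarcomere genes and 7 of the 22 energy genes, whose peaks can belong to the neighbour. Of 21755 protein-coding genes, 15344 (70.5%) had a promoter peak in both libraries. Against the other protein-coding genes the adjusted p was 0.000847 for the sarcomere list and 0.00205 for the energy list (two-sided Fisher's exact test, Benjamini-Hochberg over 25 lists). Both lists also passed against genes of matched promoter CpG content (adjusted p = 0.00125 and 0.0050, random-list permutation).

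Genes of excitation, calcium handling and cardiac transcription were open with 1 exception each. Of 21 excitation and calcium genes, 20 had a promoter peak in both libraries, led by the kinase gene Camk2d (17.7 ± 6.56), the potassium channel gene Kcnj2 (9.76 ± 2.91) and the calcium pump gene Atp2a2 (9.69 ± 2.64). Ryr2, the calcium release channel, had 3.10 ± 0.156 and Pln, the inhibitor of the pump, 1.27 ± 0.207. Sln, the atrial relative of Pln, had no peak in either library. Of 20 cardiac transcription factors, 19 had a promoter peak in both, with Esrra at 31.8 ± 16.5, Mef2a at 15.5 ± 3.81, Tead1 at 14.9 ± 0.148, Gata4 at 7.67 ± 2.35, Hand2 at 5.51 ± 1.89, Mef2c at 3.90 ± 0.0597, Nkx2-5 at 3.02 ± 0.976 and Tbx5 at 1.00 ± 0.0145. Hand1, a factor of the early left ventricle, had none. The adjusted p was 0.0222 for each of these lists (Fisher's exact test). The transcription factor call ended with a background matched on CpG content (adjusted p = 0.319, random-list permutation) and with the 5′ end of each gene as its only start site (adjusted p = 0.161, Fisher's exact test). The excitation call ended with the stricter peak list, where 18 genes had a peak (adjusted p = 0.124, Fisher's exact test).

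Genes of the fetal and atrial programmes were open in part. Of 16 fetal heart genes 13 had a promoter peak in both libraries, and of 12 atrial genes 9. Myl4, the atrial light chain, which both lists hold, had 16.1 ± 0.944, with a promoter window that overlapped another gene's. Tnni1, the troponin I of slow skeletal muscle and of the fetal heart, had 2.70 ± 0.809, close to the 2.90 ± 0.134 of its adult counterpart Tnni3. Myh7, the main ventricular myosin of the fetal mouse heart, had a peak of 0.657 in replicate 1 and none in replicate 2, and Nppa, which encodes atrial natriuretic peptide, had none in replicate 1 and 0.657 in replicate 2. Nppb had 1.89 ± 0.391. The atrial gene Pam had 7.65 ± 1.01, whereas Bmp10 and Sln had no peak in either library. Neither list could be separated from other genes (adjusted p = 0.460 for fetal and 1 for atrial genes, Fisher's exact test).

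Markers of the other cell types of the heart were open to different degrees. All 20 fibroblast genes had a promoter peak in both libraries, with the matrix genes Fn1 and Col1a1 at 9.14 ± 0.0854 and 8.23 ± 0.264 and the receptor gene Pdgfra at 8.13 ± 0.532, and so did all 13 mural and smooth muscle genes, with Myh11 at 5.52 ± 0.916. The adjusted p was 0.00495 for fibroblast and 0.0222 for mural genes (Fisher's exact test). The fibroblast call ended with the 5′ end of each gene as its only start site (adjusted p = 0.0545, Fisher's exact test). Of 25 endothelial genes 22 had a peak in both libraries, with Ets1 at 16.9 ± 4.42, Vwf at 9.96 ± 4.09 and Pecam1, whose promoter window overlapped another gene's, at 1.62 ± 0.408, and Esm1 and Plvap had none in either (adjusted p = 0.112, and 0.0402 without replicate 2, Fisher's exact test). Of 9 epicardial genes 8 had a peak in both, of which Tbx18 was highest with 5.03 ± 1.99 (adjusted p = 0.355, Fisher's exact test). Myeloid genes had a peak in both libraries in 10 of 18 cases (adjusted p = 0.244, Fisher's exact test), with Spi1 highest at 1.60 ± 0.589, and with the stricter peak list in 6 cases, fewer than all other genes (adjusted p = 0.00912, Fisher's exact test) but not than genes of the same CpG content (33.3% against 30.1%, adjusted p = 1, random-list permutation). Schwann and autonomic genes had 8 of 14 (adjusted p = 0.429, Fisher's exact test), with Egr2, a transcription factor of myelinating cells, at 8.51 ± 1.78.

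Among genes of tissues foreign to the heart, those of liver, germline, epithelia and skin mostly lacked a promoter peak shared by the libraries. Most of those of skeletal muscle and neurons had one. Lymphocyte and erythroid genes, which were listed as markers of cells within the heart, mostly lacked one too. Of 26 liver genes 4 had a promoter peak in both libraries, of 17 germline genes 3, and of 16 genes of gut, pancreas and lung epithelium 4 (adjusted p = 2.06e-07, 0.00012 and 0.000847, Fisher's exact test). These lists also passed with the CpG-matched background (adjusted p = 0.0050, 0.00125 and 0.0020, random-list permutation). Lymphocyte genes had 4 of 16, erythroid genes 4 of 13 and keratinocyte genes 4 of 12 (adjusted p = 0.000847, 0.00732 and 0.0162, Fisher's exact test), and none of these 3 passed with the CpG-matched background (adjusted p = 0.317, 0.949 and 1, random-list permutation). The lymphocyte call rested on replicate 1, since 10 of the 16 genes had a peak in replicate 2 (adjusted p = 0.512 without replicate 1, Fisher's exact test), and the keratinocyte call on replicate 2 (adjusted p = 0.154 without it, Fisher's exact test). The albumin gene Alb had no promoter peak in either library. Neither had Ptprc, a leukocyte gene of the myeloid list described above. The strongest peaks on these 6 lists were those of the liver factor Foxa3 (15.4 ± 4.98) and the oocyte gene Gdf9 (14.6 ± 6.63), and both promoter windows overlapped that of another gene, as did that of Cd3d and of no other of the 23 genes with peaks. Skeletal muscle genes had 14 of 24 (adjusted p = 0.244, Fisher's exact test), with Actn3 at 12.1 ± 2.42 from a promoter window that overlapped another gene's and the myogenic factor Myod1 at 0.934 ± 0.177, and neuronal genes 19 of 25 (adjusted p = 0.692, Fisher's exact test), with Snap25 at 6.13 ± 1.47.

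The housekeeping, cell cycle, imprinted and X inactivation and escape lists were complete. All 28 housekeeping, 25 cell cycle, 19 imprinted and 7 X inactivation and escape genes had a promoter peak in both libraries (adjusted p = 0.000719, 0.000847, 0.00495 and 0.158, Fisher's exact test), with the elongation factor gene Eef2 at 25.0 ± 5.18, the cyclin gene Ccne1 at 22.8 ± 4.30 and the imprinted gene Peg3 at 12.7 ± 6.61. The promoter windows of Eef2 and Peg3 overlapped those of other genes. With the CpG-matched background the housekeeping and cell cycle calls ended (adjusted p = 0.120 and 1, random-list permutation), and with the 5′ end of each gene as its only start site the imprinted call ended (adjusted p = 0.416, Fisher's exact test). Genes are not replicates, so the p-values of gene lists describe these 2 libraries.

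**Figure D2:**
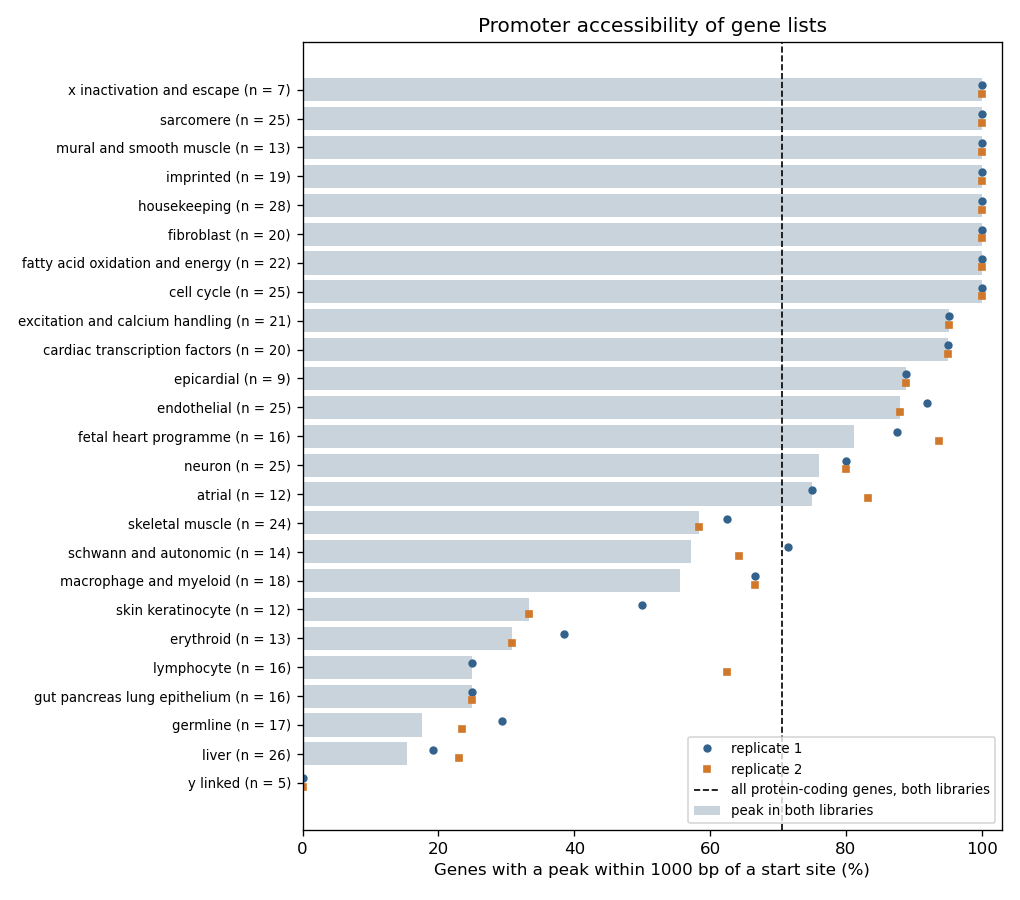
Share of the genes of each list (%, x axis) with a peak within 1000 bp of a start site. Bars give genes with a peak in both libraries, symbols the share in each library, and the dashed line the 70.5% of all protein-coding genes, with the sarcomere, fibroblast and energy lists at 100% and the liver list at 15.4%.

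The height of promoter peaks ordered the lists in another way than their presence. Housekeeping genes had median promoter values of 11.8 in replicate 1 and 18.6 in replicate 2, at the 100th percentile of 10000 random lists of protein-coding genes, and cell cycle genes had 9.19 and 12.8. Sarcomere genes, all of them open, had medians of 2.59 and 3.47, near the 2.96 and 3.64 of random lists (percentiles 43.2 and 47.7). Against random lists matched on CpG content, an alternative chosen after seeing the data, the sarcomere medians lay at percentiles 99.2 and 99.4 and those of housekeeping genes stayed at 99.99 and 100, while cell cycle genes fell within the range of random lists (77.6 and 75.8). Liver and germline genes had medians of 0 in both libraries, at percentiles 0.205 and 0.265 for liver and 1.07 and 1.22 for germline genes. With CpG matching the liver list lay at 20.7 in both libraries, within the range of random lists, and the germline list at 0.49 and 0.71. The neuron list moved from percentiles 10.9 and 9.11 to 1.07 and 0.74, and the myeloid list from 3.92 and 5.76 to 95.1 and 96.1.

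Distal sites were more frequent around the excitation and calcium, sarcomere, endothelial and fibroblast lists than around other genes of the same length, but no alternative setting kept all 4 calls. Within the gene and 50 kb on each side, excitation and calcium genes had a median of 15 distal regions shared by the libraries, endothelial genes 12, fibroblast genes 11.5 and sarcomere genes 11, against medians of 8, 7, 6.5 and 6 in random lists. The L-type calcium channel gene Cacna1c had 44, the potassium channel gene Kcnq1 42 and Ryr2 24. The fibrillin gene Fbn1 had 49, Tead1 39, Col5a1 29, Pecam1 25, Flt1 24, Gata4 23 and the sarcomere gene Ldb3 21. Of all shared regions, 92122 (72.8%) were distal, and protein-coding genes had a median of 6. Each of these 4 lists, and the Y-linked list with a median of 0, had an adjusted p of 0.050 (random-list permutation), just under the threshold. The Y-linked result was fixed in advance, since the mice were female. That list still counted in the adjustment, and the calls of the other 4 lists depend on its being counted. With a reach of 100 kb and in the stronger part of each peak list only the endothelial list stayed above (adjusted p = 0.0250 for both, random-list permutation), and with the stricter peak list none of the 25 lists passed, while 7 had an unadjusted p under 0.05 (random-list permutation). The fibroblast call also ended without either replicate (adjusted p = 0.111 without replicate 1 and 0.143 without replicate 2, random-list permutation) and the excitation call without replicate 1 (adjusted p = 0.0850, random-list permutation). Mural genes and cardiac transcription factors had medians of 11 each (adjusted p = 0.191 for both, random-list permutation), energy genes had 9 against 6 in random lists (adjusted p = 0.315, random-list permutation), and liver and germline genes had 5, the median of random lists.

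Distal peaks were enriched in motifs of factors of many tissues, and the motifs listed for muscle and heart went both ways. The insulator protein CTCF had a match in 4.78% ± 0.111 of 150 bp windows at distal peaks and in 0.128% of windows 1000 bp away, a ratio of 37.5 ± 2.46 (SD, n = 2). REST, a repressor of neuronal genes, had a ratio of 74.7 ± 8.01 from matches in 0.212% of windows, and NFI 18.4 ± 3.63. Only 0.00287% of flanks matched REST, so its ratio rests on very few control matches, and the SD does not measure that counting error. Against GC-matched windows CTCF had 98.3 ± 8.90, REST 51.7 ± 24.4 and NFI 18.8 ± 2.88. With 300 bp windows the ratios were 18.3 for CTCF, 29.4 for REST and 10.02 for NFI, so their size depended on the control and the width. The muscle E-box had a match in 15.9% ± 0.281 of windows (ratio 2.84 ± 0.0585), AP-1 in 5.41% (2.03 ± 0.155), the ERG type of ETS motif in 5.30% (1.78 ± 0.175) and TEAD in 4.44% (1.77 ± 0.156). Motifs tied to other cells were higher too, with PU.1 of myeloid cells at 1.98 ± 0.242 and the neural E-box at 1.60 ± 0.00998, as was the glucocorticoid receptor motif at 3.43 ± 1.09. That of SRF, a muscle factor, had 0.934 ± 0.0312 and was not separable from flanks (adjusted p = 0.509, exact binomial test). The motif of MEF2, a muscle factor with a site rich in A and T, was less frequent in peaks than in flanks (0.721 ± 0.0216), as was that of NKX2-5 (0.892 ± 0.0198). Against windows of the same GC content both turned, to 3.10 ± 0.134 for MEF2 and 1.26 ± 0.0222 for NKX2-5. GATA had 1.06 ± 0.0788 against flanks and 1.47 ± 0.0824 against GC-matched windows, and TBX5 was lower in both comparisons (0.696 ± 0.0572 and 0.555 ± 0.0650). In all, 16 of 30 motifs were higher and 6 lower than in flanks in both libraries (21 and 1 against GC-matched windows), from 123175 windows in replicate 1 and 120201 in replicate 2. Against flanks the larger adjusted p of the 2 libraries was 4.36e-114 for TEAD, 3.60e-31 for MEF2, which was lower, and 0.571 for GATA (two-sided exact binomial test, Benjamini-Hochberg over motifs). Windows are not replicates, so these p-values describe the 2 libraries. The reversed consensus, a control with the same bases, gave 0.586 for CTCF, 0.762 for NFI, 0.973 for AP-1, 1.03 for the ERG type of ETS motif, 0.748 for TEAD and 1.46 for the muscle E-box. For the heart motifs it gave 0.215 for MEF2, 0.864 for NKX2-5, 0.651 for GATA and 1.21 for TBX5. Reversal adds CG pairs to the CTCF, NFI and muscle E-box consensus and removes a CG pair from CREB, so for these the control differs in more than order. At promoter peaks the ratio to flanks was 11.8 ± 1.12 for NRF1, 9.47 ± 1.21 for the promoter type of ETS motif and 7.45 ± 0.814 for CREB. Each of these consensus sequences holds a CG pair. No GC-matched or reversed control was made at promoter peaks, so base content may contribute to these ratios.

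**Figure D3:**
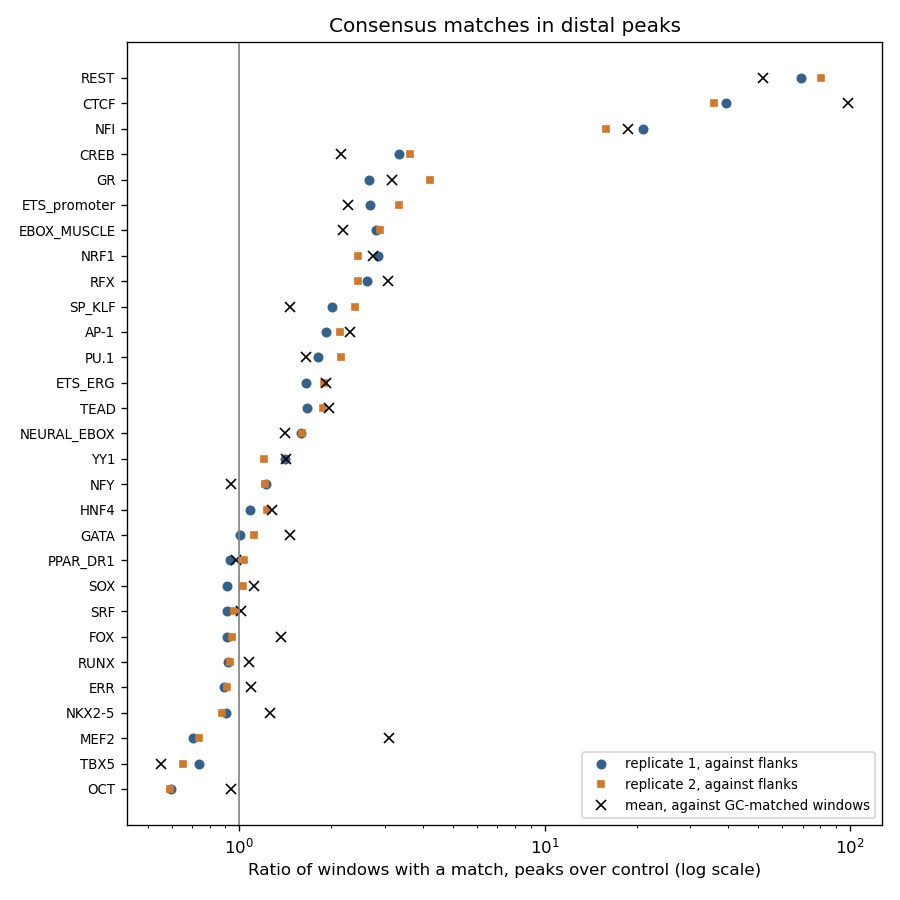
Ratio of the share of 150 bp windows with a consensus match at distal peaks to that in control windows (x axis, log scale), for each motif (y axis) except HNF1. Symbols give each library against flanks 1000 bp away and the mean of both against windows matched on GC content, with CTCF at 39.2 and 35.8 in the 2 libraries and MEF2 at 3.10 against GC-matched windows.

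Footprints, short stretches within open chromatin that were protected from cutting, lay mostly inside peaks. For some motifs they covered the middle base of most matches, and such matches are a small part of all footprints. A match counted as inside where its middle base lay in a footprint. This held for 93.6% ± 0.692 of the NRF1 matches in peaks, 88.6% ± 3.20 of CTCF, 84.5% ± 9.76 of REST and 73.2% ± 5.55 of NFI matches (SD, n = 2). It also held for 72.6% of CREB, 62.9% of SP/KLF, 56.5% of RFX and 52.2% of promoter-type ETS matches. Footprints covered 15.4% and 14.9% of peak bases. The density of matches inside footprints over that in other peak bases was 82.5 ± 11.6 for NRF1, 45.1 ± 13.1 for CTCF and 15.7 ± 4.01 for NFI. It was 1.47 ± 0.278 for the muscle E-box, 0.836 ± 0.0291 for TEAD, 0.75 ± 0.0248 for AP-1, 0.623 ± 0.111 for MEF2, 0.564 ± 0.0487 for GATA and 0.392 ± 0.0486 for the glucocorticoid receptor. The reversed consensus gave 0.823 for the muscle E-box, 0.581 for TEAD, 0.732 for AP-1 and 0.592 for MEF2. It gave 0.453 for GATA and 0.617 for the glucocorticoid receptor, the only one of these motifs that lay under its reversed consensus. Densities under 1 are therefore no sign by themselves that footprints avoid a motif. Replicate 1 had 406805 footprints and replicate 2 had 357506, with median widths of 10 and 11 bp, of which 88.9% and 88.7% lay in peaks. Of all footprints 53.0% and 60.4% overlapped one of the other library. A footprint was present in 80.4% and 76.8% of peaks, and in 31.4% and 18.0% of peaks in the lowest decile of value. Footprints had a GC content of 60.2% and 61.6%, against 54.1% and 54.0% in the other peak bases.

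Chromosome X carried fewer sites than the autosomes, and its promoter peaks were weaker. Replicate 1 had 25.9 peaks per Mb on X and 67.7 on autosomes, and replicate 2 had 24.4 and 65.8, a ratio of 0.377 ± 0.00782 (SD, n = 2). The autosome with the lowest density had 52.6 and 51.0 peaks per Mb. Over all peaks the median value on X was 0.636 ± 0.00353 of that on autosomes, but 0.968 ± 0.0140 in the stronger part of each list, where the density ratio was 0.262. A promoter peak was present at 54.6% and 53.6% of 948 X-linked protein-coding genes, against 73.2% and 72.8% of 20807 autosomal genes. The median value where a peak was present was 2.45 on X and 6.13 on autosomes in replicate 1, and 3.63 and 8.06 in replicate 2. Genes known to escape X inactivation had higher values, with Kdm6a at 31.2 ± 15.4, Kdm5c at 18.0 ± 8.84 and Ddx3x at 10.9 ± 3.57, and the non-coding genes Ftx and Xist had 13.3 ± 6.35 and 2.32 ± 0.0172. Chromosome Y held 39 peaks in replicate 1 and 26 in replicate 2, and none of 5 Y-linked genes had a promoter peak in either library (adjusted p = 0.00506, Fisher's exact test). The strongest Y peak in both libraries lay at 90744581 to 90744820 in replicate 1 (3.67) and at 90744521 to 90744800 in replicate 2 (2.80).

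Endothelial promoters were higher and neuronal promoters lower in replicate 2 than in replicate 1, relative to all promoters. The endothelial list had a median log2 ratio of replicate 2 to replicate 1 of 0.18, against -0.13 in random lists of the same peak value, and 15 of 22 genes lay above 0. Tie1, an endothelial receptor, had 1.497 in replicate 1 and 4.17 in replicate 2, the endothelial cadherin gene Cdh5 1.97 and 4.31, and the nitric oxide synthase gene Nos3 2.46 and 5.15, whereas the receptor gene Flt1 had 2.99 and 2.90. The neuron list had a median of -0.63, against -0.21 in random lists, and 6 of 19 genes lay above 0. Snap25, a protein of synaptic vesicle release, had 7.17 and 5.10, and Gad1, an enzyme of GABA synthesis, 1.69 and 1.08, whereas the kinase gene Camk2a had 2.93 and 5.97. Ratios were centred on the median of 15344 genes, a log2 ratio of 0.43, whereas the values of single genes are not centred. Their SD over these genes was 0.40. Of 23 lists these were the 2 that passed (adjusted p = 0.0253 for endothelial and 0.00920 for neuronal genes, random-list permutation). Distal regions around endothelial genes were also higher in replicate 2, with a median of 0.21 against 0.03 in random lists (adjusted p = 0.00460, random-list permutation), and those around neuronal genes had -0.09 against -0.04 (percentile 20.2). The neuronal call ended with quantile-normalised values (adjusted p = 0.0667, random-list permutation). With 1 library per heart these percentiles describe the libraries and test no difference between animals.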

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

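Chosen after seeing the data were random lists matched on gene density, promoter medians matched on CpG content, CpG matching with the stricter list, and ratios at distal regions. Of 773 alternative values of single lists and motifs, 619 kept their direction and side of the threshold, 57 no longer passed, 20 newly passed and 77 turned in direction. Of these 77 the log2 ratios of MEF2, NKX2-5, RUNX and NFY and the lymphocyte promoter median had passed before, and the sarcomere promoter median and FOX newly passed. For promoter medians the mean of the 2 libraries' percentiles was taken, which for the lymphocyte list had been 0.73 in replicate 1 and 3.95 in replicate 2. Peak overlap between the hearts (78.6%) became 69.4% at 50% reciprocal overlap, 82.1% with the stricter list and 86.9% in the stronger part of each list. The promoter share (25.8%) became 19.3% and 32.9% with windows of 500 and 2000 bp, 31.3% with the stricter list and 35.2% in the stronger part, and the density ratio of X (0.377) became 0.352 and 0.262 with the last 2 settings. Shared footprints (56.7%) became 42.8% at 50% reciprocal overlap. Lists past the promoter test (16) became 10 with CpG matching and 8 with CpG matching and the stricter list. Lists past the distal test (5) became 3 with a reach of 20 kb, 2 with 100 kb, 3 with gene density matched, 1 in the stronger part and 0 with the stricter list (random-list permutation, 7 at an unadjusted p under 0.05), and 3 to 4 without a replicate. The 5 include the Y-linked list, whose outcome was fixed in advance in female mice. Motifs higher in peaks (16) became 5 with the reversed consensus. The SP/KLF consensus reads the same reversed, so this is no control for it, and for the other 29 motifs 15 became 4. Lists that differed between the hearts (2) became 1 with quantile-normalised values and 1 at distal regions. Log2 ratios of motifs turned with GC-matched windows (MEF2 1.63, NKX2-5 0.34, RUNX 0.10, NFY -0.091, FOX 0.45, ERR 0.13, SOX 0.16, SRF 0.017), the stronger part (SOX 0.058, SRF 0.076), windows of 100 bp (PPAR 0.20) and 300 bp (SOX 0.0094, SRF 0.013) and in at least 1 case without replicate 1 and without replicate 2 (PPAR 0.052 and -0.10, SOX 0.034 and -0.14). Promoter medians turned, in percentile points from the middle, with CpG matching (lymphocyte 2.29, from percentiles 29.0 in replicate 1 and 75.6 in replicate 2, sarcomere 49.3, myeloid 45.6, fibroblast 43.9, endothelial 14.3, cardiac transcription factor -22.7) and with windows of 2000 bp (mural -2.09) and 500 bp (mural -5.78). Shares of open promoters turned, in points from other genes, with CpG matching (myeloid 20.1, skeletal muscle 2.83, neuron -1.97), the stricter list (epicardial -0.228, neuron -6.90), both (epicardial -3.01, myeloid 3.20, neuron -13.7, skeletal muscle 0.0813), the stronger part (epicardial -8.19, fetal -1.25, neuron -15.8) and windows of 500 bp (atrial -2.22, neuron -4.89). Distal counts turned, in percentile points from the middle, with gene density matched (keratinocyte 2.68), a reach of 100 kb (epicardial -27.1, germline 30.9, epithelial -0.180, imprinted -2.17) and 20 kb (cell cycle -8.93, neuron 6.32, skeletal muscle 23.6), the stricter list (epicardial -2.15, germline 16.4, skeletal muscle 41.5), the stronger part (epicardial -0.185, germline 12.0, myeloid -9.06, skeletal muscle 12.7), and in at least 1 case without replicate 1 and without replicate 2 (germline 6.11 and 20.1, epithelial -3.37 and 12.4, liver 28.4 and 33.1, lymphocyte 19.5 and -40.1, skeletal muscle 11.5 and 7.41, epicardial 34.9 and -2.11, Schwann -43.2 and 27.5). Log2 ratios between the hearts turned, as differences from random lists, at distal regions (lymphocyte -0.14, excitation -0.092, keratinocyte -0.081, X inactivation -0.061, cardiac transcription factor -0.046, atrial -0.039, fetal -0.036, sarcomere -0.0045, imprinted -0.0038, liver 0.017, erythroid 0.023, cell cycle 0.040, housekeeping 0.042) and with quantile-normalised values (Schwann -0.046, keratinocyte -0.0081). The cause was not tested. Footprints could not be ranked, since their value is constant, and summed cut counts were not run. No paired analysis was possible because there was 1 group. The number of reads is unknown, so what depth limits was not tested, also for the lowest decile of peaks, of which 27.4% and 39.5% were shared.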

Other observations

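The tests on escape genes, on quantile-normalised values, on the share of cardiomyocytes and on lymphocyte genes in 1 library were chosen only after the result was seen. Some lymphocyte promoters had a peak in replicate 2 only, which did not pass after adjustment over lists. Genes with a peak in replicate 2 and none in replicate 1 included the T cell genes Cd8a (0.649), Cd3e (0.455) and Cd3g (0.438), the B cell gene Ms4a1 (0.261) and the interleukin receptor gene Il7r (0.185). All 6 lymphocyte genes with a peak in 1 library only had it in replicate 2, against 296 of the other protein-coding genes in replicate 2 only and 396 in replicate 1 only (Fisher's exact test, p = 0.00638, adjusted over 25 lists p = 0.159). Of the 4 genes with a peak in both libraries 1 was higher in replicate 2 after centring, and distal regions around the list had a median log2 ratio of -0.22 against -0.08 in random lists (adjusted p = 0.704, random-list permutation). The highest values of the list were those of genes open in both hearts, Lck (7.63 ± 1.49) and Pax5 (7.22 ± 0.745).

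Promoters on X that had a peak reached 0.399 and 0.450 of the autosomal median in the 2 libraries. Against 10000 autosomal sets of the same CpG content the mean ratio was still 0.543, which argues against CpG content as the whole cause. At genes with no other gene of the same symbol stem within 1 Mb it was 0.419, which argues against reads lost at local gene copies. The escape genes Kdm6a, Kdm5c, Ddx3x and Eif2s3x had a median 1.99 times that of autosomal promoters and 1.31 times that of autosomal sets of the same CpG content. They lay at percentiles 66.8 and 89.2 of those autosomal sets in the 2 libraries, and at percentile 100 of CpG-matched sets of X genes in both. The sets were matched on CpG content only, so other traits of these genes could also raise their rank. A candidate explanation, as a hypothesis, is 1 silenced X chromosome per cell. Part of the first ratio went with CpG content, and without male hearts here a difference in gene content between X and autosomes stays open.

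The endothelial list was higher and the neuron list lower in replicate 2. With quantile-normalised values the endothelial list lay at percentile 99.93, which argues against a difference in the spread of values. The neuron list stayed low at percentile 0.28, but its call ended after adjustment (adjusted p = 0.0667, random-list permutation), so for neuronal genes this cannot be told apart. Its median moved from -0.63 (SD 0.54) to -0.31 (SD 0.54). Random lists can move with the normalisation as well, so these 2 medians do not measure how much of the difference went. Matched on value and CpG content the lists lay at percentiles 99.81 and 0.04, which argues against CpG content. A lower share of cardiomyocytes in replicate 2 may raise all other cell types. Without quantile normalisation the fibroblast, mural and myeloid lists reached at most percentile 93.71 at promoters or around genes, and with it 93.83 (fibroblast promoters). This lies between the bounds set for and against a lower share, so it cannot be told apart from a change in the endothelium alone. Sarcomere promoters lay towards higher values in replicate 2 (percentile 98.6, adjusted p = 0.222, random-list permutation), the other way than fewer cardiomyocytes would give. Matched on value and CpG content, these promoters lay at percentile 91.08. By contrast, distal regions around sarcomere and excitation genes lay at percentiles 46.05 and 3.04 (adjusted p = 0.937 and 0.701, random-list permutation). A difference between the 2 animals was not tested.

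Some of the strongest peaks were listed in 1 library only, at promoter sites in or beside Rps19 (13.3), Gatad2b (12.0), Lims1 (11.3), Atf3 (10.97) and Lrch4 (10.8) in replicate 1 and Hnrnpl (18.5), Atf5 (15.04), Etfdh (12.97), Relb (12.9) and Ctdsp2 (12.8) in replicate 2. Of the top decile of such peaks, 29.6% lay within 150 bp of a peak of the other library and 45.8% held a base listed there (means of both), so neither a call placed differently nor a site open in 1 heart only could account for all of them. This decile began at values of 0.610 in replicate 1 and 0.834 in replicate 2, with medians of 0.749 and 1.08. The medians of all peaks were 0.680 and 0.851, so these shares mostly describe peaks of ordinary height. All 10 named peaks held a listed base of the other library and 8 lay near one of its peaks, so these sites were not without signal there. For the top decile as a whole the explanations cannot be told apart, since both shares lie between the bounds set beforehand. The strongest with neither a near peak nor a listed base had 1.79 in replicate 1 (X, 170017961 to 170018140) and 3.03 in replicate 2 (chromosome 15, 83226541 to 83226700).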
